A study of Arabidopsis thaliana with 60 samples.

How the data were processed

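Cytosine methylation was measured by whole-genome bisulfite sequencing in endosperm, the nourishing tissue of the seed, of Arabidopsis thaliana at 4 days after pollination. The series holds 60 libraries. The 54 chromatin immunoprecipitation and input libraries were not analysed here, and all values come from the 6 bisulfite libraries. Per the labels' protocols, endosperm nuclei were isolated by INTACT, an affinity capture of nuclei tagged in a chosen cell type, their DNA was sheared by sonication, converted with the EpiTect Fast kit and made into libraries with the NuGEN Ovation Ultralow Methyl-Seq system. Mothers were plants of the Col-0 background that carried the nuclear tag and the dde2 mutation. The labels put the libraries into 3 groups of 2 by the pollen parent, which are called WT, osd1 and osd1adm. Nothing in the labels says that replicates came from separate plants, so every p-value measures only the spread between these samples, which may be technical.

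The authors deposited 18 files, 1 for each library and cytosine context (CG, CHG and CHH, where H is A, C or T), holding counts of methylated and unmethylated reads at each cytosine of both strands. The counts were not normalised, and cytosines without reads were listed at 0. Per the submitters' processing notes, Bismark was among the tools and TAIR10 was the genome build. The version of Bismark, read trimming, removal of duplicate reads and handling of reads with several matches were not given in the sources used here, so PCR copies may be counted more than 1 time and near-identical repeats may share reads. The files list 5567714 CG, 6093657 CHG and 31198379 CHH cytosines on chromosomes 1 to 5. Each library covered between 93.1% and 97.6% of them, and the mean depth of 3.78 to 5.39 reads per cytosine is too low for single cytosines to be compared, so counts were summed over regions.

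The methylation level of a library was the number of methylated reads over all reads, and group values are means with the sample SD (n = 2 libraries). Groups were compared by a two-sided exact permutation test, whose smallest p for 2 libraries against 2 is 0.333, so that no level could pass 0.05. Chloroplast and mitochondrial cytosines stayed out of all levels. Regions were tiles of 300 bp and gene flanks, a flank being 1 kb upstream pooled with 1 kb downstream of a protein-coding gene. Regions with at least 20 calls in each library were tested with a quasi-binomial logistic model of the methylated and unmethylated counts. The spread was estimated over all 3 groups and moderated with limma's squeezeVar, p-values were adjusted by the Benjamini-Hochberg method, and a region was called at an adjusted p under 0.05. The counts varied between replicates by more than sampling of independent calls, with a median overdispersion of 4.22 in CG, 3.94 in CHG and 15.0 in CHH flanks. Replicates were checked for duplicate deposits. They differed, with chi-square values of 2.14 to 6.98 per tile where calls are taken as independent, and each library was counted as a separate sample. Replicates were not more alike than libraries of different crosses. In CG, Pearson r across tiles was 0.814 for WT, 0.850 for osd1 and 0.852 for osd1adm replicates. It was 0.820 to 0.860 for pairs from different crosses. In CHH, r was 0.0217 for WT, -0.0079 for osd1 and 0.109 for osd1adm replicates, and 0.0061 to 0.182 for pairs from different crosses. CHH levels of single tiles were thus hardly reproduced between replicates.

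Gene names and neighbours came from a RefSeq table of the TAIR10.1 assembly, none of whose coordinates are given. Of 625 tRNA genes in it, 604 had the conserved T-arm bases at the table's positions in the files' numbering, against at most 66 at any other shift of up to 20 bp. Positions given are those of tiles in TAIR10. No annotation of transposable elements was used here, and the planned tests of transposable elements were not computed. In their place, 41233 tiles whose pooled CHG level over all 6 libraries was at least 10% were taken as CHG-methylated tiles, and 10236 segments were made by merging neighbouring ones. A set of 17917 CG-only tiles had a pooled CG level of at least 30% and a CHG level of at most 3%. No mappability was assessed.

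Flanks were also tested as 9 gene lists with limma's camera on log2((methylated + 1) / (unmethylated + 1)), with a preset correlation of 0.01 and with an estimated correlation, adjusted over 81 tests. Members were also adjusted over each list alone, separately in each of the 81 tests, so some can pass by chance. The lists were paternally expressed imprinted genes, maternally expressed imprinted genes, type I MADS-box genes, DNA and H3K9 methylation genes, Polycomb genes, endosperm regulators, seed storage genes (a marker of late seed development), seed coat genes (a marker of the tissue around the endosperm) and genes demethylated in the central cell. The text names the 3 flanks with the largest rise and the 3 with the largest fall among those called for each comparison and context, every called list member, and the imprinted loci PHE1, FWA, MEA, FIS2, ADM, AHL10 and SUVH7. Other genes and tiles named were chosen after their values were seen. The groups, tests, gene lists, this rule and the first set of alternatives were fixed before the data were examined. The CHG-methylated tiles, merged segments, the CHG to CG ratio and the added alternatives were chosen after.

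The alternatives chosen in advance were edgeR's quasi-likelihood test, only the compared groups in the fit, 100-bp tiles, minimums of 10 and 50 calls, a minimum difference in level of 0.1, thinning to the shallowest library, a term for the replicate number, mean levels of cytosines with at least 4 reads, no cytosines of high coverage, a correction by chloroplast methylation, and each library left out in turn. Alternatives added after seeing the data left out 100-kb bins with a raised background, kept only chromosomes 1 to 3, or subtracted the local background of unmethylated tiles. A bin had a raised background where the CHH level of its unmethylated tiles lay over 2 times the library's median. Bins with too few unmethylated tiles for an estimate were left out as well. This kept 401 of 1193 bins, which held 5596 of the 41233 CHG-methylated tiles. Values from bins without raised background thus cover a small part of these tiles. The tests were checked on simulated counts for osd1 against WT, with 50 regions raised by each size. At 20 percentage points the quasi-binomial test recovered 78% of CG, 86% of CHG and 90% of CHH flanks, with 8, 13 and 9 false calls among all simulated flanks. Highly methylated regions were not among those raised, and no falls were simulated. Shifts shared by regions of a library were not simulated either. Recovery of falls in methylated flanks was thus not measured. It recovered 0% of CG and CHG tiles and 30% of CHH tiles at that size, and edgeR recovered 0% of CG, 6% of CHG and 0% of CHH flanks. At 40 points edgeR still recovered 0% of CG and CHH flanks, so its counts of 0 there say little. It recovered 0% of tiles in every context at up to 40 points. The quasi-binomial test recovered 2% of CG, 0% of CHG and 86% of CHH tiles at 40 points. Counts of 0 tiles by edgeR, and by the quasi-binomial test in CG and CHG, thus say little. Camera called 1 of 1 raised list and 0 of the unchanged ones. This single list says little on recovery or false calls for the real lists, whose estimated correlation reached 0.848. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, arrow 21.0.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9.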

Results

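DNA methylation was measured in F1 endosperm from 3 crosses that shared a diploid Col-0 mother, with 2 bisulfite libraries each. WT seeds came from pollen of diploid Col-0. The osd1 seeds came from pollen of osd1-1, a mutant that omits a meiotic division and makes unreduced pollen, so that the endosperm carries an excess of paternal genomes. The osd1adm seeds came from osd1-1 adm-2 pollen, which also lacks ADMETOS (ADM), a paternally expressed imprinted gene whose loss rescues triploid seeds from abortion. The WT libraries held 227759284 and 172316327 cytosine calls on chromosomes 1 to 5, the osd1 libraries 168743527 and 220689733, and the osd1adm libraries 231005393 and 162134075. In each library, 14.4% to 16.9% of 100-kb bins had a raised background. The median background of these bins lay above the library's median in all contexts. On chromosome 5 of WT replicate 2 and chromosome 4 of osd1adm replicate 2, CG methylation of CHG-methylated tiles reached 71.6% and 71.9%.

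The comparison of osd1 with WT asked what an excess of paternal genomes does to endosperm methylation. CHG methylation of heterochromatin was lower in osd1, whereas CG methylation of the same tiles lay between the WT libraries. In the CHG-methylated tiles, of which 30850 of 41233 lie in pericentromeres, the CHG level was 26.0% ± 5.17 in WT and 17.9% ± 0.711 in osd1 (SD, n = 2). The CG level of these tiles was 45.2% ± 11.4 in WT and 42.6% ± 1.47 in osd1. CHG methylation of pseudogene bodies was 17.9% and 26.1% in the WT libraries and 14.8% ± 0.654 in osd1, and that of gene bodies was 1.92% and 2.53% in the WT libraries and 1.77% ± 0.0736 in osd1.

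Both osd1 libraries lay below both WT libraries in the CHG level of these tiles, a difference of -8.11 percentage points with an exact permutation p of 0.333, the smallest that 2 against 2 allows. The CHH level of the tiles was 3.67% ± 1.34 in WT and 2.29% ± 0.390 in osd1, a difference of -1.38 points (exact permutation p = 0.333), and the groups overlapped in CHH on chromosomes 1, 2 and 4. Over chromosomes 1 to 5, the CHG level was 4.18% and 6.20% in the WT libraries and 3.67% and 3.65% in the osd1 libraries, a difference of -1.53 points (exact permutation p = 0.333). The genome-wide CG level was 12.4% ± 2.97 in WT and 12.0% ± 0.0808 in osd1, and the CHH level was 1.91% ± 0.647 and 1.48% ± 0.0195, with exact permutation p = 1.00 for both. WT replicate 2 set much of these sizes. Without it the difference was -4.45 points for CHG, -0.429 for CHH and 5.48 for CG in the CHG-methylated tiles, -0.520 for genome-wide CHG, 1.67 for genome-wide CG and 0.0270 for genome-wide CHH. Without WT replicate 1 these were -11.8, -2.33, -10.7, -2.54, -2.53 and -0.888. After subtraction of the local background the CHH difference in the CHG-methylated tiles was -0.415 points.

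**Figure D1:**
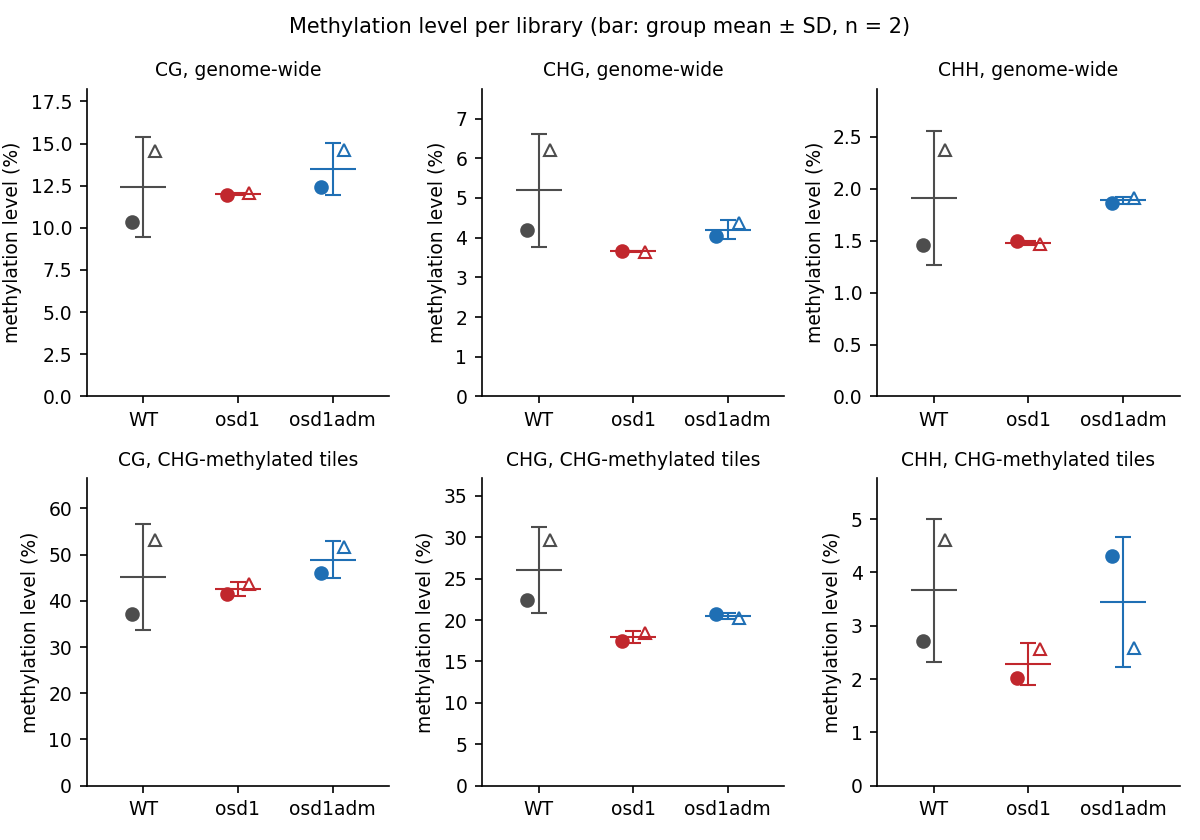
Methylation level in percent for each library (points) with the group mean and SD (lines), for CG, CHG and CHH over chromosomes 1 to 5 and in the 41233 CHG-methylated tiles. In CHG, both osd1 libraries lie below both WT libraries in the CHG-methylated tiles (17.4% and 18.4% against 22.4% and 29.7%), and the osd1adm libraries lie between them (20.8% and 20.3%).

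CHG methylation relative to CG methylation separated the groups with less spread. In CHG-methylated tiles the CHG to CG ratio was 0.604 and 0.558 in the WT libraries and 0.420 and 0.423 in the osd1 libraries, a difference of -0.160 in the means. It was 0.548 ± 0.0107 in pericentromeres of WT and 0.389 ± 0.0040 in those of osd1, and in the bodies of pseudogenes it was 0.595 ± 0.0348 and 0.434 ± 0.0026. Both osd1 libraries lay below both WT libraries on each of chromosomes 1 to 5. In the CG-only tiles, typical of methylated gene bodies, the CG level was 39.3% ± 4.28 in WT and 39.5% ± 0.370 in osd1. This difference rested on the WT libraries, at 3.21 points without WT replicate 2 and -2.85 without WT replicate 1. Both osd1 libraries were higher on chromosomes 1 and 3, by 2.91 and 2.27 points, and the difference was -4.69 on chromosome 5, where WT replicate 2 held 53.1%.

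**Figure D2:**
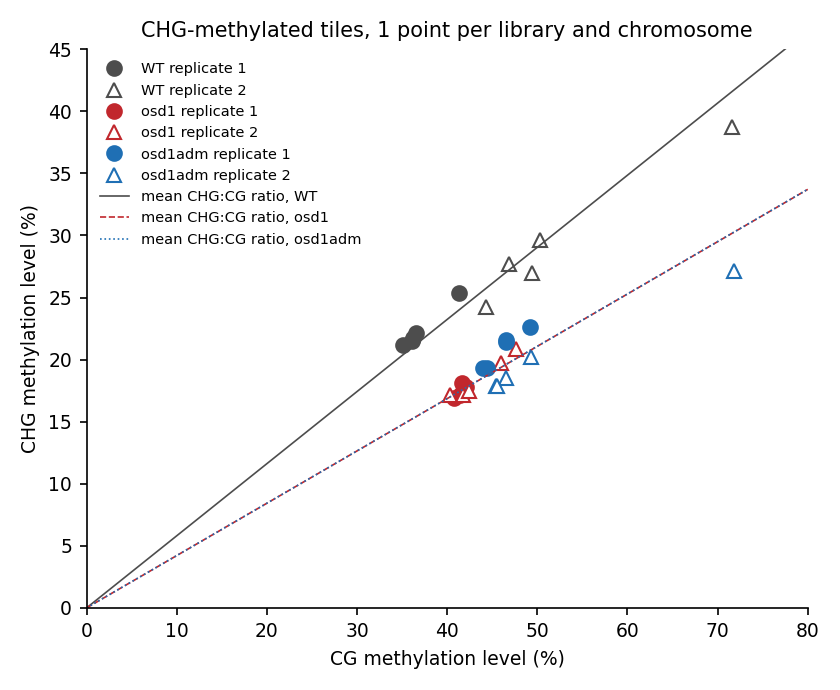
CHG level against CG level (both in percent) of CHG-methylated tiles, with 1 point for each library and chromosome and lines at each group's mean ratio. The lines lie at a ratio of 0.581 in WT, 0.421 in osd1 and 0.422 in osd1adm. The points above 70% CG lie below their group's line, at 0.542 in WT replicate 2 and 0.378 in osd1adm replicate 2.

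Segments of merged CHG-methylated tiles showed the same direction across the genome. Of 10236 segments, 46.2% had both osd1 libraries below both WT libraries in CHG and 3.59% had both above. The median difference was -6.84 percentage points. Chance gives 16.7% each way for a single segment. All segments come from the same libraries and share their level shifts, so they are not independent tests. In CHH, 29.6% had both below and 6.59% both above. In CG, 12.99% of 8929 segments had both below and 14.5% both above. The quasi-binomial model called 0 of 293814 tiles in CHG. An unadjusted p under 0.05 was held by 17993 (6.12%), of which 13631 were lower in osd1. Over all comparisons, 4.63% to 6.42% of tiles and 3.38% to 7.83% of flanks had such a p in this model. Among unchanged simulated regions of osd1 against WT the share was 5.08% to 5.87%. Such counts alone therefore do not show a difference. The main direction of CHG tiles at that unadjusted p turned when either osd1 library was left out. It stayed lower in osd1 when a WT or an osd1adm library was left out. The quasi-binomial model called 0 of 272471 tiles in CG and 0 of 391847 in CHH, with 13697 and 18294 at an unadjusted p under 0.05. edgeR called 0 tiles in every context, with between 6352 and 18224 at an unadjusted p under 0.05 over all comparisons. It recovered 0% of simulated tiles at every size, so these counts of 0 say little.

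**Figure D3:**
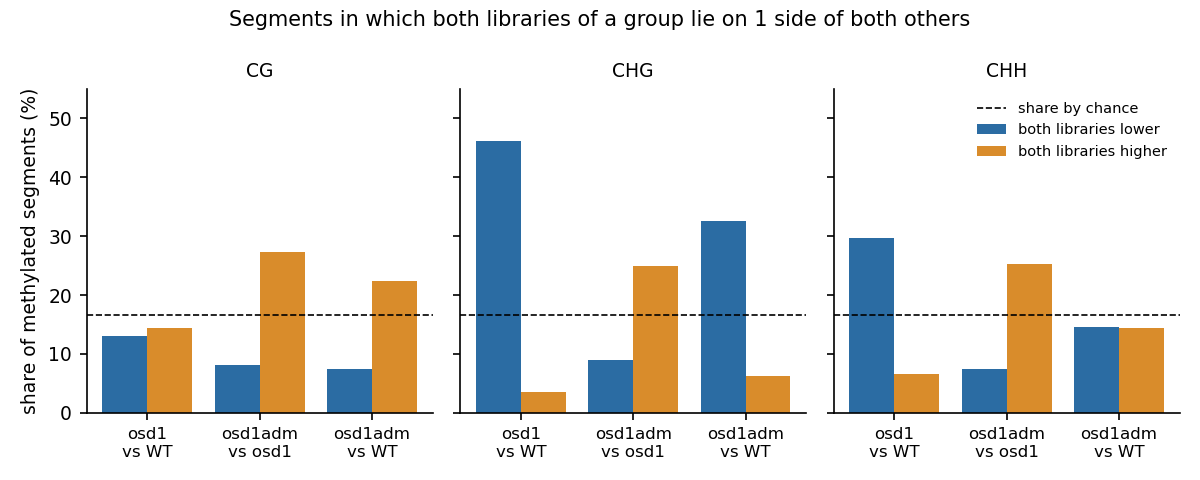
Share of merged CHG-methylated segments (percent) in which both libraries of the first group lie below or above both of the second, by context and comparison. The line lies at the 16.7% that chance gives for a single segment. For CHG in osd1 against WT, 46.2% of segments were lower and 3.59% higher.

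A single gene flank passed the test. CG methylation around AT5G28090, a protein-coding gene of no given name between the pseudogenes AT5G28085 and AT5G28100 on chromosome 5, was lower in osd1. Its flank level was 78.9% ± 1.31 in WT and 42.0% ± 3.31 in osd1 (SD, n = 2, quasi-binomial model moderated with limma, adjusted p = 0.0336), with 213 to 863 calls in each library. The WT libraries held 77.9% and 79.8%. However, chromosome 5 of WT replicate 2 held 71.6% CG in CHG-methylated tiles, against 36.2% in WT replicate 1. WT replicate 2 is thus an uncertain replicate on this chromosome, and the small WT SD may mislead. Among the tiles along the locus with at least 20 CG calls in each library, the CG gap between the means was widest at 10100101 to 10100400, within the flank (86.2% ± 8.64 in WT and 38.3% ± 19.5 in osd1). It was narrowest at 10101901 to 10102200, within the gene (71.2% ± 2.16 and 69.3% ± 2.98). CHG methylation of the flank was 47.3% ± 3.24 in WT and 19.9% ± 1.80 in osd1 (adjusted p = 0.888), and CHH methylation was 5.29% ± 0.789 and 1.91% ± 0.449 (adjusted p = 0.930). The CHG difference of -27.4 points was not called, although most simulated rises of 20 points in CHG flanks were. Counts of 0 flanks thus do not exclude falls of this size. The CG call was lost with only WT and osd1 in the fit (adjusted p = 0.260), and without WT replicate 2 (0.889), osd1 replicate 1 (0.549), osd1 replicate 2 (0.998), osd1adm replicate 1 (0.289) or osd1adm replicate 2 (0.256). edgeR gave an adjusted p of 0.928, but it recovered 0% of simulated CG flanks even at a rise of 40 points, so this value does not bear on the call. Over all alternatives the adjusted p of the flank ranged from 0.000929, without the bins of raised background, to 0.998.

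**Figure D4:**
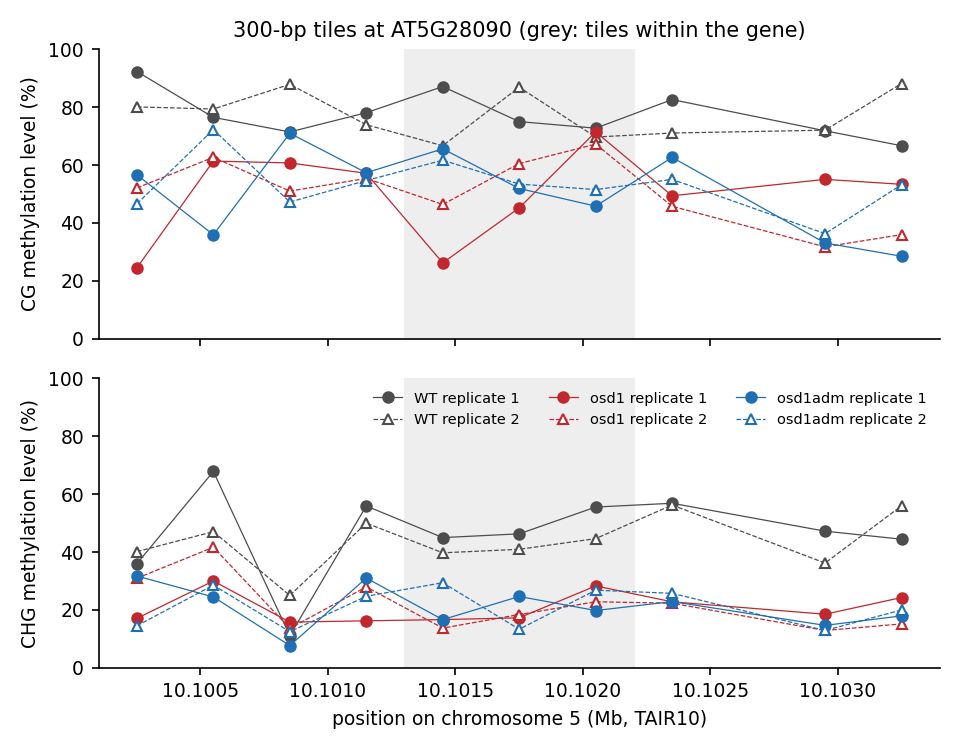
CG and CHG methylation level (percent) of 300-bp tiles along chromosome 5 around AT5G28090 for the 6 libraries, with tiles within the gene on grey. The WT libraries lie highest in most flank tiles, as at 10102801 to 10103100, where CG is 71.8% and 72.0% in WT and between 31.7% and 55.05% in the other libraries.

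Of 27345 flanks tested in CG, 1402 had an unadjusted p under 0.05, of which 946 were higher in osd1, but without WT replicate 1 only 496 of 2167 were higher. In CHG, 0 of 27338 flanks were called by the quasi-binomial model, with 1425 at an unadjusted p under 0.05, of which 1013 were lower in osd1, but without osd1 replicate 1 only 394 of 1058 were lower, and without osd1 replicate 2 only 282 of 1060. In CHH, 0 of 27366 were called, with 924 at an unadjusted p under 0.05. edgeR called 0 flanks in every context, with between 833 and 1768 at an unadjusted p under 0.05 over all comparisons. Without WT replicate 1 the model called 9 CG flanks and 4 CHG flanks, all lower in osd1.

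Among the gene lists, none passed the camera test in osd1 against WT. Paternally expressed imprinted genes had a CHG flank level of 6.20% ± 1.47 in WT and 3.603% ± 0.169 in osd1, lower for 21 of 24 members with a median of -1.73 percentage points (p = 0.00948, adjusted p = 0.254, adjusted p = 0.967 with an estimated correlation). The median log2 difference was -0.749 for these flanks and -0.166 for all flanks, which were thus also lower. FXG1 held 9.94% ± 0.0330 CHG in WT and 5.66% ± 0.597 in osd1, and AT2G36560 held 10.4% ± 4.02 and 3.11% ± 0.481. Type I MADS-box genes, a family of transcription factors active in endosperm, had a CG flank level of 4.32% ± 0.944 in WT and 6.94% ± 0.441 in osd1. It was higher for 17 of 22 members (p = 0.00750, adjusted p = 0.254, and 0.967 with an estimated correlation). Their median log2 difference was 0.682, against 0.0925 for all flanks. AGL34 held 5.91% ± 1.06 CG in WT and 14.7% ± 6.70 in osd1, and AGL87 held 10.5% ± 2.66 and 17.5% ± 0.0640. Of either list, 0 members were called over all flanks and 0 adjusted over the list alone in these tests.

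DNA and H3K9 methylation genes had a CHG flank level of 2.70% ± 0.0560 in WT and 1.57% ± 0.0230 in osd1, lower for 20 of 31 (camera, adjusted p = 0.448). Their median log2 difference was -0.662, against -0.166 for all flanks. In CHH 21 of 31 were lower (camera, adjusted p = 0.254). In CHG, 0 members were called over all flanks and 1 adjusted over the list alone. This was CMT3, the CHG methyltransferase, at 15.3% and 6.01% in WT. The osd1 libraries had 0 methylated reads among 131 and 185 calls, which allows levels of up to 2.29% and 1.62% by counting error only. CMT3 flank CG and CHH levels in WT replicate 1 were 15.2% and 12.7%, close to its CHG level. SUVH9, which recruits the RNA-directed DNA methylation machinery, held 7.85% ± 0.560 CHG in WT and 1.35% ± 1.31 in osd1. Seed storage genes had a CG level of 0.887% and 5.90% in the WT libraries and 1.13% ± 0.0520 in osd1, and WT replicate 2 also held 6.92% CHG and 6.06% CHH there. Endosperm regulators had a CHG level of 1.35% ± 1.04 and 1.70% ± 0.822 (camera, adjusted p = 0.448). The CG levels in WT and osd1 were 8.16% ± 0.664 and 9.44% ± 0.153 for seed coat genes, 10.7% ± 3.43 and 8.96% ± 0.274 for maternally expressed genes, 4.93% ± 1.76 and 4.47% ± 0.747 for Polycomb genes, and 7.29% ± 2.83 and 7.40% ± 0.837 for genes demethylated in the central cell.

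None of the imprinted loci fixed for naming passed the test in osd1 against WT, with adjusted p-values of 0.903 or more in CG. The CG flank level of PHE1, a paternally expressed MADS-box gene, was 1.77% ± 0.0540 in WT and 3.45% ± 1.05 in osd1. FWA, a maternally expressed homeobox gene silenced by methylated repeats, held 10.5% ± 3.97 and 14.8% ± 4.44. MEA and FIS2, maternally expressed Polycomb genes, held 7.04% ± 1.98 and 10.2% ± 10.0 in WT and 4.71% ± 3.85 and 5.31% ± 0.0590 in osd1. ADM held 2.99% ± 3.71 and 6.18% ± 1.67, AHL10, which encodes an AT-hook protein, held 20.9% ± 11.3 and 20.3% ± 2.33, and SUVH7, a SET-domain gene, held 1.64% ± 0.342 and 1.10% ± 0.937. In WT replicate 2 the CHH levels of the FIS2, AHL10 and FWA flanks were 15.02%, 12.8% and 9.71%, against 0.938%, 0.484% and 0.485% in WT replicate 1.

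The comparison of osd1adm with osd1 asked what loss of paternal ADM changes under paternal excess. Over all CHG-methylated tiles methylation was slightly higher in osd1adm, but in each context the groups overlapped in parts of the genome. In CHG-methylated tiles the CHG level was 17.9% ± 0.711 in osd1 and 20.5% ± 0.350 in osd1adm, the CG level was 42.6% ± 1.47 and 48.9% ± 4.00, and the CHH level was 2.29% ± 0.390 and 3.45% ± 1.22 (SD, n = 2). The differences of 2.59, 6.32 and 1.16 percentage points each had an exact permutation p of 0.333. Without osd1adm replicate 2 the CG difference was 3.50 points and the CHH difference 2.02, and without osd1adm replicate 1 the CHH difference was 0.295. After subtraction of the local background the CHH levels overlapped, at 0.942% and 0.992% in osd1 and 1.44% and 0.728% in osd1adm. In bins without raised background the CG levels overlapped, at 41.6% and 42.7% in osd1 and 42.5% and 53.5% in osd1adm. By chromosome the groups overlapped in CG on chromosomes 2 and 4, and in CHG and CHH on chromosomes 1, 2 and 4. The CHG to CG ratio of these tiles did not separate the crosses, at 0.421 ± 0.0021 in osd1 and 0.422 ± 0.0416 in osd1adm.

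Over chromosomes 1 to 5 the osd1adm libraries lay above the osd1 libraries by 1.51 percentage points in CG, 0.544 in CHG and 0.407 in CHH, each with an exact permutation p of 0.333. The CG difference was 0.422 points without osd1adm replicate 2 and 2.59 without osd1adm replicate 1. In CHG, 24.98% of segments had both osd1adm libraries above both osd1 libraries and 8.90% both below. Chance gives 16.7% for a single segment. The shares were 25.3% and 7.44% in CHH and 27.3% and 8.09% in CG. After subtraction of the local background the differences were 0.214 points in CHG and 0.0437 in CHH, and the correction by chloroplast methylation gave -0.687 and -0.857. That correction left osd1adm replicate 2 at -1.10% in CHH, an impossible level, so these 2 values measure no methylation difference. The quasi-binomial model called 0 tiles, with 13519, 13609 and 21540 at an unadjusted p under 0.05 in CG, CHG and CHH. It called 0 flanks, with 1397, 1340 and 1220, and edgeR called 0 of either.

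No gene list passed the camera test in osd1adm against osd1. Adjusted over the list alone, FIE among Polycomb genes passed in CHG and AGL23 among type I MADS-box genes passed in CG. In these tests 0 members were called over all flanks. The adjustment over the list alone was repeated in 81 tests, so passing it is weak evidence. FIE, a subunit of the Polycomb repressive complex, held 1.59% and 0.573% CHG in osd1 and 8.78% and 7.14% in osd1adm, with CHH at 1.69% and 1.09% against 6.50% and 4.47%. AGL23 held 3.88% and 18.4% CG in osd1 and 0.482% and 0.905% in osd1adm, with 20.8% CHG and 13.6% CHH in osd1 replicate 2. Genes demethylated in the central cell had a CG level of 7.40% ± 0.837 in osd1 and 10.1% ± 2.12 in osd1adm, higher for 9 of 13 (adjusted p = 0.649). Paternally expressed genes held 3.603% ± 0.169 and 3.84% ± 0.592 CHG (adjusted p = 0.821). The ADM flank held 5.00% and 7.36% CG in osd1 and 10.9% and 5.94% in osd1adm (adjusted p = 0.949). PHE1 was at 2.65% ± 0.303 CG in osd1adm, FWA at 18.3% ± 6.20, MEA at 6.19% ± 2.80, FIS2 at 3.66% ± 3.04, AHL10 at 16.6% ± 0.918 and SUVH7 at 3.54% ± 0.712, with adjusted p-values against osd1 of 0.926 or more.

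The comparison of osd1adm with WT asked whether endosperm that lacks paternal ADM resembles that of a diploid cross. Over all CHG-methylated tiles the CHG level lay below the WT libraries, while CG methylation overlapped them. The CHG level of CHG-methylated tiles was 26.0% ± 5.17 in WT and 20.5% ± 0.350 in osd1adm (SD, n = 2), with both osd1adm libraries lower. By chromosome both were lower on chromosomes 2 and 3, and the groups overlapped on chromosomes 1, 4 and 5 and in the 9729 tiles richest in GC (20.9% and 21.3% against 20.5% and 31.5% in WT). The CHG to CG ratio was 0.604 and 0.558 in WT and 0.451 and 0.392 in osd1adm. The pericentromeric CHG level was 15.6% and 23.1% in the WT libraries and 15.5% and 14.7% in the osd1adm libraries, and that of pseudogene bodies was 17.9% and 26.1% in WT and 17.5% ± 0.0293 in osd1adm, so that both lay close to WT replicate 1.

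The difference in the CHG-methylated tiles was -5.52 percentage points (exact permutation p = 0.333), and it was -1.87 without WT replicate 2 and -9.18 without WT replicate 1. The genome-wide differences were 1.07 points in CG, -0.984 in CHG and -0.0238 in CHH, with exact permutation p-values of 0.667, 0.667 and 1.00. The CG difference was -1.03 without WT replicate 1 and -0.0115 without osd1adm replicate 2, and the CHG difference was 0.0237 without WT replicate 2. The CHH difference was a balance of 0.434 without WT replicate 2 and -0.481 without WT replicate 1. In CHG, 32.6% of segments had both osd1adm libraries below both WT libraries and 6.20% both above, with a median of -4.69 percentage points. In CHH the shares were 14.6% and 14.4%, both under the 16.7% that chance gives for a single segment. In CG, 22.4% had both above and 7.36% both below.

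In osd1adm against WT the quasi-binomial model called 0 tiles, with 17339, 18863 and 24935 at an unadjusted p under 0.05 in CG, CHG and CHH, and 0 flanks, with 2141, 1742 and 1403. edgeR called 0 of either. The flank of AT5G28090 held 78.9% ± 1.31 CG in WT and 45.6% ± 2.29 in osd1adm (limma-moderated model, adjusted p = 0.114), and 47.3% ± 3.24 and 19.7% ± 3.14 CHG (adjusted p = 0.768). The limit given for chromosome 5 of WT replicate 2 applies here too. Without WT replicate 1, 1 CG flank and 2 CHG flanks were called, and without the bins of raised background 1 was called in CG, 1 in CHG and 0 in CHH, both times that of AT5G28090 (adjusted p = 0.00383 in CG and 0.00874 in CHG).

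No gene list passed in osd1adm against WT. Seed storage genes had the lowest p in CG (p = 0.00650, adjusted p = 0.254, and 0.967 with an estimated correlation), at 0.887% and 5.90% in WT and 1.09% ± 0.0170 in osd1adm. Polycomb genes held 4.93% ± 1.76 and 5.91% ± 0.0510 CG, where 0 members were called over all flanks and 1, FIE, adjusted over the list alone, at 4.18% and 4.85% in WT and 15.1% and 14.4% in osd1adm. FIE was also the member that passed over the list alone in CHH, at 1.16% ± 0.272 and 5.48% ± 1.43. Paternally expressed genes held 6.20% ± 1.47 and 3.84% ± 0.592 CHG, lower for 14 of 24 (adjusted p = 0.517). Endosperm regulators held 4.32% ± 1.70 and 6.14% ± 0.270 CG (adjusted p = 0.517). Of these, ICE1 held 0 methylated reads among 419 and 230 calls in WT. That allows levels of up to 0.716% and 1.30% by counting error only. In osd1adm ICE1 held 4.74% and 2.80% CG. Seed coat genes held 8.16% ± 0.664 and 9.11% ± 1.24 CG, maternally expressed genes 10.7% ± 3.43 and 12.5% ± 3.39, and type I MADS-box genes 4.32% ± 0.944 and 6.75% ± 1.02. The imprinted loci fixed for naming had adjusted p-values of 0.647 or more in CG. Over all 3 comparisons, 0 of 81 list tests passed with the preset correlation and 0 with the estimated one, and 6 passed without WT replicate 1.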

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

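The tests of explanations in this part were chosen after the results were seen. Organelle cytosines stayed out of the levels of the report. Organelle cytosines served for the chloroplast correction and for tests of explanations in this part. Several of their levels lay above the higher WT library and others below the lower one. In the chloroplast, osd1adm replicate 2 held 2.89% CG, 3.06% CHG and 2.98% CHH, against at most 0.871%, 0.7998% and 0.861% in WT. Both osd1 libraries lay below both WT libraries in the chloroplast, with CG at 0.410% and 0.492% against 0.516% and 0.871%, CHG at 0.449% and 0.484% against 0.522% and 0.7998%, and CHH at 0.534% and 0.552% against 0.561% and 0.861%. The chloroplast CHH level of osd1adm replicate 1, 0.544%, was also below both WT libraries. Chloroplast levels come from different sets of cytosines. In CG, 44.7% and 44.6% had no reads in the osd1 libraries and 44.1% in osd1adm replicate 2, against 7.99% and 9.02% in WT. In the mitochondria, CG was 25.3% and 33.4% in the osd1 libraries and 29.2% in osd1adm replicate 2, against 11.2% and 18.8% in WT. These levels come from different sets of cytosines, since 69.8% of mitochondrial CG cytosines had no reads in both osd1 libraries and 41.4% in osd1adm replicate 2, against 13.1% and 37.3% in WT. Mitochondrial CHG was 13.4% in osd1 replicate 2 and 12.5% in osd1adm replicate 2, against 7.09% and 11.3% in WT, and CHH was 3.73% in osd1adm replicate 2, against 1.35% and 3.62%. Mitochondrial levels below both WT libraries were CHH in the osd1 libraries (1.04% and 1.26%) and CG, CHG and CHH in osd1adm replicate 1 (10.1%, 4.62% and 1.22%).

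The CHG to CG ratio of CHG-methylated tiles was lower in the osd1 and osd1adm libraries than in both WT libraries. DNA of another tissue in the WT libraries, such as seed coat or embryo, could raise their methylation. Nuclei were captured by an endosperm tag, which selects against other tissues, and the purity of the capture was not tested here. However, WT replicate 1 had the lowest CG level of all libraries (37.1%) and WT replicate 2 the highest, so the CG level leaves this open. Processing that differed between libraries also stays open. The share of chloroplast CG cytosines without reads was 7.99% and 9.02% in WT, 44.7% and 44.6% in osd1, and 4.87% and 44.1% in osd1adm, and osd1adm replicate 1, alone on the WT side of that split, had a ratio of 0.451. The ratio in mitochondrial cytosines split in the same way, at 0.633 and 0.601 in WT, 0.412 and 0.402 in osd1, and 0.455 and 0.427 in osd1adm. Whether these reads came from mitochondria or from nuclear copies of their DNA was not tested, so they do not decide between processing and the crosses. Paternal genome excess and the osd1 pollen line, which this design confounds, stay open and were not tested.

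Background methylation was raised in stretches of the genome that differed between libraries. Of 12 pairs of libraries from different crosses, 7 shared more raised bins than expected and 5 shared fewer, from 62 in osd1 replicate 1 and osd1adm replicate 1 (34.0 expected) to 6 in WT replicate 1 and osd1 replicate 1 (30.2 expected). Incomplete bisulfite conversion may account for it, as it raises all contexts alike, and the median CG to CHH ratio in raised bins was 0.976. These bins were chosen by their CHH level, in tiles selected for low CG and CHG levels. That choice limits how far CG could exceed CHH, so the ratio is weak evidence. Why the raised background was confined to stretches of a chromosome was not tested. Methylation shared by the WT cross or the osd1 cross is argued against, since their replicates shared 11 raised bins where 59.1 were expected. For osd1adm, whose replicates shared 60 where 29.1 were expected, it stays open, though 1 pair from different crosses shared 62. No biological explanation beyond the crosses was tested.

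CG methylation was high over a whole chromosome in 1 library, on chromosome 5 of WT replicate 2 and chromosome 4 of osd1adm replicate 2. Incomplete conversion is argued against, since the CHH level of unmethylated tiles on these chromosomes was 0.910% and 0.815%. Methylation shared by a cross is argued against by the other replicates, at 36.2% on chromosome 5 in WT replicate 1 and 44.5% on chromosome 4 in osd1adm replicate 1. Counts of another library on that chromosome cannot be told apart from a property of the library, since a library of the same cross could give them. Coverage goes with such a replacement. CG cytosines without reads made up 11.04% of chromosome 5 in WT replicate 2, against 4.73% to 5.29% of its other chromosomes. They made up 9.69% of chromosome 4 in osd1adm replicate 2, against 4.37% to 5.40%. Each of the 2 chromosomes was the first listed in its file. In the other libraries the first-listed chromosome held 35.1% (WT replicate 1), 40.7% and 40.3% (osd1) and 46.5% CG (osd1adm replicate 1). A first place in the file alone thus did not go with high CG. The CHG to CG ratio was 0.542 on chromosome 5 of WT replicate 2, where its other chromosomes had 0.546 to 0.591, and 0.378 on chromosome 4 of osd1adm replicate 2, against 0.393 to 0.410.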

How the results depend on the processing

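The alternatives by background bins, local background and chromosomes, and every leave-1-out value of the gene lists and of CHG-methylated and CG-only tiles, were chosen after the results were seen. Of the values under alternatives chosen in advance, 293 stayed within the spread or on the same side of the threshold and 14 moved. Of those added later, 178 stayed and 11 moved. Of those that stayed, 126 and 36 were tile counts of 0, which could hardly move at the recovery given below, so they show no stability. Leaving out 1 of 2 libraries shifts a group mean by less than the group's SD. Levels with 1 library left out could thus hardly move, even where the sign of a difference turned, and show no stability either. The planned tests of transposable elements were not run, since no annotation of them was used here. All 162 tile counts under alternatives were 0, as were 122 of 135 flank counts, the highest being 9. The CHG to CG ratio of CHG-methylated tiles kept its direction against WT, between -0.137 and -0.182 for osd1 and between -0.130 and -0.189 for osd1adm with 1 library left out. That direction could not turn, as both WT libraries lay above every other library. Correction by chloroplast methylation turned the osd1adm minus osd1 difference to -0.687 points in CHG and -0.857 in CHH, and gave -1.11 for osd1adm minus WT in CHH, since osd1adm replicate 2 had the highest chloroplast level, 2.98% in CHH. Its corrected CHH level was -1.10%, so the correction does not suit this library. Local background correction gave 0.214 in CHG, 0.0437 in CHH and 1.74 for CHG of CHG-methylated tiles in osd1adm minus osd1. Chromosomes 1 to 3 gave 0.454 in CHH and 1.81 for CHG of those tiles, and bins without raised background gave 0.254 in CHH. CG of those tiles on chromosomes 1 to 3 was 41.5% and 43.3% in osd1 and 45.6% and 47.2% in osd1adm. The WT libraries held 37.6% and 47.2% there. The CG gap between osd1adm and osd1 was smaller there than over all chromosomes. By chromosome the gap was 14.5 points on chromosome 4, where osd1adm replicate 2 held 71.9%, and 3.37 to 5.31 points on the others. The larger gap over all chromosomes thus rested on chromosome 4. The cause of the other moves was not tested. The count of CG flanks in osd1 against WT, 1 in the fit as designed, was 0 with edgeR, which recovered 0% of simulated CG flanks at up to 40 points, 0 with only the 2 groups compared and 0 on chromosomes 1 to 3, which exclude the called gene. With 1 library left out it ranged from 0 to 9. It ranged from 0 to 1 for CG flanks in osd1adm against WT, from 0 to 4 for CHG flanks in osd1 against WT, and from 0 to 2 for CHG flanks in osd1adm against WT, the highest always without WT replicate 1. Bins without raised background gave 1 for each of these last 3, in each case AT5G28090. The gene list tests passed in 0 to 6 cases with 1 library left out, 6 without WT replicate 1, including seed storage genes in regions of raised background in WT replicate 2, and the cause was not tested further. With a term for the replicate number (replicate block), 1 CG flank was called in osd1 against WT, 0 flanks or tiles elsewhere and 0 list tests. The numbers do not pair the samples, as deviations of same-numbered libraries had correlations between -0.0942 and 0.0217. At the depth of these libraries a rise of 20 points was recovered in 0% of simulated CG and CHG tiles, while 76% and 94% had an unadjusted p under 0.05. Depth was not separated from the number of libraries or of tests.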

Other observations

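The sequence contexts in this part were compared only after the other results were seen. CHG methylation differs by the middle base, since CMT3 and its partner SUVH4 act less on CCG than on CAG and CTG. In CHG-methylated tiles, CAG and CTG exceeded CCG by 5.37 and 4.46 percentage points in the WT libraries, 2.26 and 2.48 in the osd1 libraries, and 3.33 and 3.94 in the osd1adm libraries. The means were 4.91 ± 0.645, 2.37 ± 0.160 and 3.63 ± 0.432 (SD, n = 2), so in points the osd1adm libraries lay between the other groups without overlap. As a ratio of CAG and CTG to CCG the order was lost, at 1.30 and 1.17 in WT, 1.14 and 1.15 in osd1, and 1.18 and 1.23 in osd1adm. Over chromosomes 1 to 5 the excess was 0.685 and 0.702 points in WT, 0.158 and 0.187 in osd1, and 0.345 and 0.4999 in osd1adm. Background did not cancel in full, since in unmethylated tiles CAG and CTG exceeded CCG by 0.153 and 0.265 points in WT, 0.101 and 0.106 in osd1, and 0.119 and 0.142 in osd1adm. The CCG level of CHG-methylated tiles was 22.1% ± 5.73 in WT, 16.0% ± 0.578 in osd1 and 17.6% ± 0.688 in osd1adm.

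In CHH, the contexts CAA and CTA, preferred by CMT2, held 5.08% and 7.63% in the CHG-methylated tiles of WT, 3.44% and 4.00% in osd1, and 6.87% and 3.59% in osd1adm. Their excess over the other CHH contexts was 3.67 ± 0.631 points in WT, 1.95 ± 0.0148 in osd1 and 2.43 ± 1.49 in osd1adm. In CG-only tiles, CHG exceeded CHH by 0.192 ± 0.0243 points in WT, 0.197 ± 0.0137 in osd1 and 0.0836 ± 0.0030 in osd1adm. In bins without raised background the excess was larger, at 0.262 ± 0.0329, 0.257 ± 0.0065 and 0.166 ± 0.0072. CG-only tiles held 42.4% ± 3.78 CG in osd1adm, at 39.8% and 45.1% in its libraries. On chromosome 4 these tiles held 41.2% in osd1adm replicate 1 and 57.7% in osd1adm replicate 2. A tile across an end of FWA, at 13038301 to 13038600 on chromosome 4, held 20.5% and 21.2% in WT, 60.0% and 22.2% in osd1, and 32.8% and 47.0% in osd1adm, with 75 or more calls in each library. The 47.0% comes from osd1adm replicate 2, whose chromosome 4 held 71.9% CG in CHG-methylated tiles.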
